A study of Mus musculus with 9 samples.

How the data were processed

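Spinal cord of C57BL/6 mice was sampled in 3 groups of 3 mice, Control, EAE, and EAE given EHP-101 at 20 mg/kg by mouth, and each mouse gave 1 RNA library. Per the labels' protocols, RNA was isolated with QIAzol and a lipid tissue kit, 1 µg was used for poly-A selected stranded libraries, and sequencing on an Illumina HiSeq gave single-end reads of 50 bp. The deposited table holds read counts per gene, not normalised, under Entrez gene identifiers, per the file headers. Trimmomatic 0.36, HISAT2 2.1.0, featureCounts 1.6.1, DESeq2 1.20.0 and genome build mm10 are named per the submitters' processing notes, without the role of each. The strand setting, the handling of multiply mapped reads, the time of sampling and the length of treatment are not given in the sources used here.

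Of 27179 identifiers 25275 received a symbol from a RefSeq table of assembly GRCm38.p6, and the 1904 others held between 0.311% and 0.619% of the counts of a library. Coordinates are those of the deposited table in mm10, counted from 1. Libraries held 30448507 to 32661741 counts. In R 4.3.3, genes were kept by the edgeR 4.0.16 function filterByExpr with the group factor, which left 16749 genes. Libraries were scaled by TMM factors, and a quasi-likelihood model with 1 mean per group was fitted to all 9 libraries (prior degrees of freedom 5.28). The 3 contrasts were EAE against Control, EAE+EHP-101 against EAE and EAE+EHP-101 against Control. Genes with an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested) were called, and SE is the size of the log2 fold change divided by the root of its F statistic. CPM values use the scaled library sizes. The p-values measure the spread between these samples of 1 experiment.

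The lists of genes, the contrasts, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per contrast, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the 2 groups' libraries, up to 4 members with the smallest p of each list described, the genes Tenm4, Gjc3, Olig2, Cnr1, Cnr2, Pparg, Mbp, Gfap and Cd4 whatever their values, and the 10 largest falls and rises among genes called in EAE and called in the opposite direction in treated mice. Gene names of the predicted kind, pseudogenes and receptor segments were not named. Among the 4 members per list, those whose call held with each library left out were preferred, a choice made after the values were seen. S100a8, S100a9, Xist, Ddx3y and the mitochondrial genes were named outside this rule, after the data were seen, for checks of the libraries. A few of the genes this rule selects are not reported.

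The 43 lists covered T cells, B and plasma cells, monocytes and macrophages, neutrophils, 2 states of microglia, antigen presentation by class I and II, interferon responses, complement, chemokines, cytokines, adhesion, 2 states of astrocytes, myelin, progenitors, cholesterol synthesis, neurons, motor neurons, interneurons, synapse, neuronal injury, endothelium, pericytes and fibroblasts, cilia, Schwann cells, dorsal root ganglion, erythroid cells, muscle, proliferation, hypoxia, PPAR targets, the endocannabinoid system, NRF2 and oxidative stress, glucocorticoid response, immediate early genes, heat shock, respiration, mitochondrially encoded genes, alternative macrophage activation, and 3 genes recalled from the study itself. They held 571 genes, 525 of them tested, and 12 genes stood in 2 or more lists. Each list was tested with camera of limma 3.58.1 on voom values at the preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of 1 contrast. Counts adjusted over the list alone use only the p-values of its members.

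The pipeline was tested on simulated data, drawn from the mean and dispersion of each gene, with 200 changed genes. For EAE against Control edgeR recovered 58.2%, 80.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 9 false calls over 16749 genes. For EAE+EHP-101 against EAE the shares were 56.7%, 70.1% and 92.4% with 12 false calls, and for EAE+EHP-101 against Control 59.7%, 86.6% and 95.5% with 6. The real data had many more changes, with 6191 genes called for EAE against Control, so these rates need not hold there. In each contrast the set test called the shifted list and 0 of 30 lists without a shift. Genes were drawn independently there, so this does not show how often the set test calls correlated lists falsely. The MHC class I list, for one, had an estimated correlation of 0.876 for EAE against Control. Overlaps between contrasts that share libraries were set beside 50 simulated data sets without group differences and 50 with EAE and treated mice drawn at their common mean, and beside the number that independent lists of the same sizes would share.

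Alternatives were DESeq2 size factors, library totals and upper quartile factors in edgeR, the Wald test of DESeq2 1.42.0, limma voom, no filter except a count above 0, at least 10 counts in 3 libraries, only the 6 libraries of the 2 groups compared, a block on replicate number, a 2-fold minimum, and each library left out in turn. Removing the trend of each library with gene length or with transcript GC content (loess, span 0.5), in the gene fits and in the set tests, was added after the data were seen.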

Results

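Gene expression was measured by RNA sequencing in the spinal cord of 9 C57BL/6 mice in 3 groups of 3 mice. The groups were Control mice, mice with experimental autoimmune encephalomyelitis (EAE), an immune-mediated mouse model of multiple sclerosis, and mice with EAE given EHP-101 by mouth at 20 mg/kg (EAE+EHP-101, here also called treated). EHP-101 is a compound under a code name, described elsewhere as an activator of the nuclear receptor PPAR gamma and of the cannabinoid receptor encoded by Cnr2. The deposited values were read counts per gene, and the design asks which transcripts change in EAE and which of them move when the compound is given. Libraries held between 30448507 counts (treated replicate 2) and 32661741 counts (EAE replicate 1), spread over 19695 to 20093 genes with a count. Values per group are given below as normalised CPM (counts scaled to a common library size), mean ± SD with n = 3. Fold changes carry the standard error (SE) of their log2 value.

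The groups separated along the first principal component of log2 CPM, which held 67.0% of the variance. Control libraries scored from -47.2 to -40.9 and EAE libraries from 36.0 to 50.1. Treated replicates 2 and 3 lay between them at 8.36 and 15.2, and treated replicate 1 stood nearer the Controls at -22.2. Libraries of 1 group differed by more than sampling noise in every pair (chi-square per degree of freedom 6.36 to 26.1), so every library counted as 1 sample. Total counts and the percentages of counts in mitochondrially encoded genes, in the 10 most counted genes and in haemoglobin genes were compared in 12 exact permutation tests, 2-sided, where the smallest p that 3 against 3 allows is 0.1, so that none could pass. Total counts of all 3 EAE libraries exceeded those of all 3 treated libraries, and the haemoglobin share of all 3 Controls exceeded that of all 3 treated libraries (each exact p = 0.1, adjusted 0.6). Skeletal muscle genes summed to 62.6 CPM in Control replicate 1 and to between 3.38 and 5.60 CPM in the other libraries. The neutrophil transcripts S100a8 and S100a9 were highest in treated replicate 1, at 15.7 and 29.5 CPM.

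**Figure D1:**
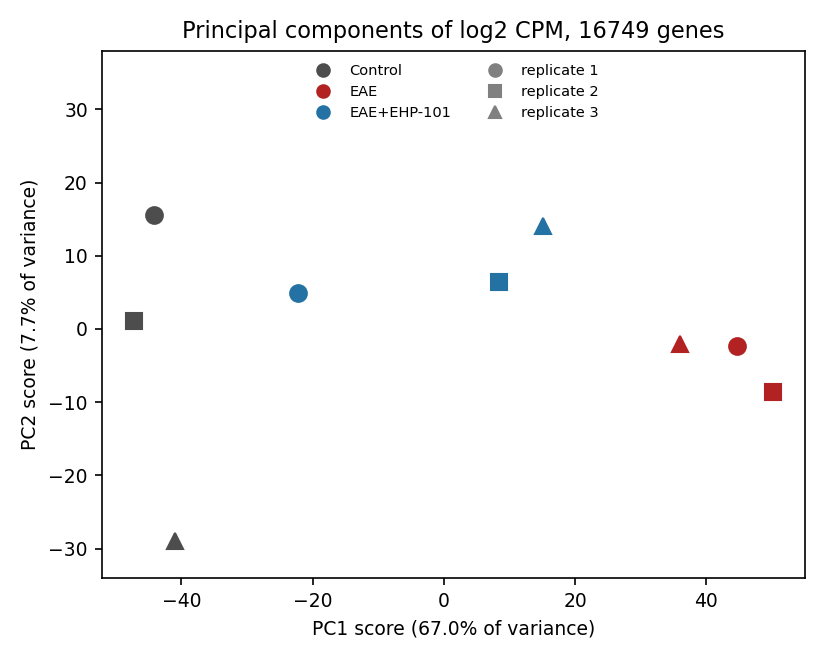
Scores of the 9 libraries on the first principal component (67.0% of variance, horizontal axis) and the second (7.70%, vertical axis) of log2 CPM over the 16749 genes tested, coloured by group with a symbol per replicate. Controls lie at -47.2 to -40.9 on the first component, EAE libraries at 36.0 to 50.1, and treated libraries at -22.2, 8.36 and 15.2.

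EAE was first compared with Control, to ask how the disease model changes the cord. Antigen presentation genes were among the largest rises. H2-Aa, a chain of the class II major histocompatibility complex (MHC), was higher 187-fold (log2 7.55, SE 0.89, adjusted p = 0.000142), with 1.02 ± 0.385 CPM in Control and 191 ± 36.8 CPM in EAE. Cd74, the invariant chain that accompanies class II molecules, went from 1.997 ± 0.602 to 342 ± 26.0 CPM, a rise of 171-fold (log2 7.42, SE 0.88). Transcripts of activated microglia and phagocytes rose with them. Among these were Clec7a, a receptor for beta-glucans, by 53.9-fold (log2 5.75, SE 0.53) and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, by 53.6-fold (log2 5.75, SE 0.50). Falls were smaller, such as that of Glra1, a subunit of the inhibitory glycine receptor, from 108 ± 15.3 to 40.9 ± 14.0 CPM, lower by 2.63-fold (log2 -1.39, SE 0.21). Kdr, an endothelial receptor for vascular endothelial growth factor, was lower by 2.71-fold (log2 -1.44, SE 0.26). Of 16749 genes tested, 6191 passed an adjusted p of 0.05, 3391 higher and 2800 lower in EAE. At least 2-fold were 1011 of the rises against 174 of the falls.

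The 10 largest rises under the naming rule also held the class II chains H2-Ab1 (146-fold) and H2-Eb1 (72.2-fold). Beside them stood the interferon-induced chemokine Cxcl9 (181-fold), the protease inhibitor Cst7 (86.4-fold), the integrin Itgax (71.6-fold) and the leukocyte receptor Lilrb4a (49.7-fold), with adjusted p between 1.13e-05 and 0.000403. Cxcl9 (gene 17329, chromosome 5 from 92321331 to 92328079 in mm10) rested on 8 counts over the Control libraries against 1582 in EAE, a ratio of 189.9 with an exact 95% interval of 96.1 to 441 for counting error alone. Cd74 (gene 16149, chromosome 18 from 60803849 to 60812652) stood at 341, 317 and 368 CPM in the 3 EAE libraries. The 10 largest falls were led by Frem3, an extracellular matrix protein, lower by 4.56-fold (log2 -2.19, SE 0.36), and Oprm1 (gene 18390, chromosome 10 from 6788601 to 7038209), the mu opioid receptor, lower by 3.14-fold (log2 -1.65, SE 0.22). The potassium channel gene Kcnh7 fell by 2.93-fold, Hoxc9 by 2.79-fold, Lingo4 by 2.59-fold, the endothelial cadherin gene Cdh5 by 2.54-fold and Pi15 by 2.53-fold. The call of Hoxc9 ended without Control replicate 2 or EAE replicate 1 (adjusted p = 0.0667 and 0.0738). All falls named here and above stayed called with the gene length trend of each library removed, at adjusted p up to 0.0253.

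Lymphocyte and myeloid lists rose in EAE. In the T cell list 18 of 18 (18 adjusted over the list alone) genes rose, with a median of 19.1-fold. Among them were the T cell receptor complex gene Cd3g (log2 5.45, SE 0.58), Cd6 (log2 5.68, SE 0.73) and Cd28 (log2 3.73, SE 0.49). Cd4 was higher 16.8-fold (log2 4.07, SE 0.57). Of the 11 genes of the B and plasma cell list only 4 passed the filter and were tested. All 4 (4 adjusted over the list alone) rose, led by Cd22 (log2 5.04, SE 0.57). Of the infiltrating monocyte and macrophage genes 8 of 13 (9 adjusted over the list alone) rose, including the lysozyme gene Lyz2 from 9.36 ± 1.19 to 436 ± 91.2 CPM, Ms4a7 (log2 5.35, SE 0.31) and the chemokine receptor gene Ccr2 (log2 4.64, SE 0.46). Set tests against all other genes gave adjusted p = 3.46e-10, 0.0221 and 0.000244 for these 3 lists. Each had adjusted p = 0.322 with an estimated correlation. The B and plasma cell call ended without Control replicate 3 (adjusted p = 0.0577). Among neutrophil genes 1 of 10 (1 adjusted over the list alone) rose, Csf3r, the receptor for granulocyte colony-stimulating factor (log2 2.07, SE 0.23). The list passed at adjusted p = 0.0308, and adjusted p = 0.433 with an estimated correlation.

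Both of the lists fixed for microglia rose. Each library held RNA of cord tissue, so a list named for a cell type does not tell which cells carried its transcripts. Nor does it tell whether the number of those cells changed. The disease-associated microglia list had 17 of 18 (17 adjusted over the list alone) genes higher. They included Gpnmb (gene 93695, chromosome 6 from 49036518 to 49058182) from 4.26 ± 0.143 to 113 ± 35.5 CPM, the lysosomal protease gene Ctsd (log2 1.95, SE 0.15), the galectin gene Lgals3 (log2 3.18, SE 0.25) and the signalling adaptor gene Tyrobp (log2 2.87, SE 0.24). The homeostatic microglia list had 8 of 12 (8 adjusted over the list alone) higher. They included Olfml3 (log2 1.56, SE 0.14), the fractalkine receptor gene Cx3cr1 (log2 1.61, SE 0.17) and Tmem119 (log2 1.46, SE 0.16). Set test values were 2.02e-12 and 3.72e-05, and adjusted p = 0.322 with an estimated correlation for both. The reactive astrocyte list rose in 15 of 15 (15 adjusted over the list alone) genes, such as Serpina3n (log2 2.90, SE 0.25), Lcn2 (log2 3.81, SE 0.36) and the intermediate filament gene Vim (log2 2.08, SE 0.22). Gfap, the main astrocyte filament, rose by 1.73-fold (log2 0.79, SE 0.15). That list passed at adjusted p = 3.46e-10, and adjusted p = 0.322 with an estimated correlation. Of 12 homeostatic astrocyte genes 2 rose (2 adjusted over the list alone), Aldh1l1 (log2 0.50, SE 0.07) and the water channel gene Aqp4 (log2 0.52, SE 0.13). This list did not pass (adjusted p = 0.689). The call of Aqp4 ended without Control replicate 2 (adjusted p = 0.0562) or EAE replicate 2 (adjusted p = 0.05002).

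Antigen presentation, interferon, complement and signalling lists moved the same way. The MHC class II list rose in 10 of 10 (10 adjusted over the list alone) genes and the MHC class I list in 12 of 12 (12 adjusted over the list alone), with H2-K1 (log2 2.87, SE 0.32) and the immunoproteasome gene Psmb8 (log2 3.05, SE 0.33). The type I interferon response list rose in 18 of 18 (18 adjusted over the list alone), with Bst2 (log2 2.75, SE 0.28). The interferon gamma response list rose in 12 of 13 (12 adjusted over the list alone), with Gbp2 (log2 3.27, SE 0.40) and Cxcl10 (log2 3.75, SE 0.50). All 15 tested complement genes rose (15 adjusted over the list alone), the first component genes C1qa (log2 3.05, SE 0.24) and C1qb (log2 2.74, SE 0.22) among them. Chemokine genes rose in 11 of 12 (11 adjusted over the list alone), with Ccl4 (log2 4.91, SE 0.34) and Ccl3 (log2 4.65, SE 0.39). Cytokine genes rose in 7 of 9 (7 adjusted over the list alone), with Il1a (log2 2.37, SE 0.23) and Il1b (log2 4.58, SE 0.57). Leukocyte adhesion and migration genes rose in 10 of 12 (11 adjusted over the list alone), with Itgb7 (log2 2.36, SE 0.22) and Icam1 (log2 2.47, SE 0.27). The alternative macrophage activation list had 6 of 10 (7 adjusted over the list alone) rise, with Il4ra (log2 1.10, SE 0.10) and the scavenger receptor gene Msr1 (log2 4.18, SE 0.42). The proliferation list had 11 of 17 (12 adjusted over the list alone) rise, with Top2a (log2 2.24, SE 0.29) and Cdk1 (log2 1.55, SE 0.22). Set test adjusted p ran from 1.27e-11 (complement) to 0.00110 (alternative macrophage activation). Those with an estimated correlation were adjusted p = 0.301 for proliferation, 0.352 for interferon gamma and 0.322 for the other lists of this paragraph.

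Vascular, stromal, sterol and neuronal lists changed in different directions. In the pericyte and fibroblast list 8 of 14 (9 adjusted over the list alone) genes rose, led by the collagen genes Col3a1 (log2 3.11, SE 0.18) and Col1a2 (log2 1.15, SE 0.09) and by Lum (log2 2.60, SE 0.23), and 1 of the 14 fell (2 adjusted over the list alone). Endothelial genes fell in 11 of 14 (11 adjusted over the list alone). They included Cdh5, the transporter gene Abcb1a (log2 -1.06, SE 0.18) and the receptor gene Tek (log2 -1.003, SE 0.18). Cholesterol synthesis genes fell in 18 of 20 (18 adjusted over the list alone), with a median of 1.53-fold. Among them were Lss (log2 -0.89, SE 0.12) and Insig1 (log2 -0.75, SE 0.11). Synapse genes fell in 9 of 18 (10 adjusted over the list alone), with the GABA receptor gene Gabrb2 (log2 -0.72, SE 0.09) and the glutamate receptor gene Grin2a (log2 -1.13, SE 0.17) beside Glra1. Set tests gave adjusted p = 0.000410, 3.72e-05, 7.03e-10 and 5.16e-05 for these 4 lists. The same lists had adjusted p = 0.361, 0.361, 0.322 and 0.322 with an estimated correlation.

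The libraries' trend with gene length ran with the group, at a correlation of 0.244 to 0.410 in Controls and -0.327 to -0.259 in EAE. With this trend removed the endothelial list had 11 of 14 genes lower, the cholesterol synthesis list 19 of 20 and the synapse list 6 of 18, where the synapse median went from log2 -0.29 to -0.15. The 3 lists then passed at adjusted p = 1.69e-06, 8.38e-13 and 0.000829, and not with an estimated correlation (adjusted p = 0.291, 0.262 and 0.295). The mitochondrial respiration list had 12 of 20 (15 adjusted over the list alone) genes higher (set test adjusted p = 0.00191, and adjusted p = 0.476 with an estimated correlation), and 0 of 20 with the length trend removed, which ended its call (adjusted p = 0.672). Its 4 genes first by p, Ndufa2 (log2 0.47, SE 0.07), Cox4i1, Cox6c and Sdhb, lost their calls with the length trend removed, at adjusted p = 0.0688, 0.814, 0.579 and 0.178.

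The myelin and progenitor lists did not pass the set test. In the myelin list 4 of 20 rose and 3 fell (4 and 3 adjusted over the list alone). Mag (log2 0.28, SE 0.06) and Cldn11 (log2 0.51, SE 0.11) were higher and Gjc3, a connexin, lower (log2 -0.32, SE 0.07, adjusted p = 0.00436). Mbp, which encodes myelin basic protein, had log2 -0.02 (SE 0.11, adjusted p = 0.927) at 16615 ± 2905 CPM in Control. Of the 16 progenitor genes 2 rose and 2 fell (2 and 2 adjusted over the list alone). Tenm4 (gene 23966, chromosome 7 from 96210637 to 96908554) was lower by 1.96-fold (log2 -0.97, SE 0.14) and Ptprz1 lower (log2 -0.44, SE 0.07). Olig2 was at log2 0.02 (SE 0.13, adjusted p = 0.897). Tenm4, Gjc3 and Olig2 were recalled as chosen by the study on these samples, so their 2 falls of 3 (2 adjusted over the list alone) are not independent evidence of a direction. Neither the myelin list (adjusted p = 0.6704), the progenitor list (0.902) nor these 3 genes (0.0940) passed the set test. The progenitor list's median, 0.02, and mean, -0.02, differed in sign. The neuron list had 3 of 14 lower (3 adjusted over the list alone), led by Elavl4 (log2 -0.46, SE 0.06). The interneuron list had 4 of 12 lower and 1 higher (4 and 1 adjusted over the list alone), with the glutamate transporter gene Slc17a6 (log2 -0.49, SE 0.08) and the glycine transporter gene Slc6a5 (log2 -1.24, SE 0.28). Neither passed (adjusted p = 0.352 and 0.0714). Neither did the lists for motor neurons (0.689), neuronal injury (0.146, with the stress factor gene Atf3 higher at log2 2.32, SE 0.34), cilia (0.411), Schwann cells (0.6704), dorsal root ganglion (0.434), erythroid cells (0.306) or skeletal muscle (0.443). The glucocorticoid (0.0824), immediate early (0.352), heat shock (0.624) and mitochondrially encoded (0.388) lists did not pass either.

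In all, 24 of the 43 lists passed for EAE against Control, 21 upward and 3 downward, none with an estimated correlation (adjusted p 0.301 to 0.476). With the length trend removed 2 of these calls ended, and 3 of the lists given above as not passing passed. All 24 passed with the rotation test fry, which asks only whether a list's genes move one way. Median, mean and test differed in sign for the neuron (median 0.00, mean -0.06) and mitochondrially encoded (-0.09 and 0.00) lists. The count of rises was 2160 without EAE replicate 2, and removing the length trend left 1696 falls in place of 2800. Genes with near-identical copies, such as the H2 genes, Lyz2, Lilrb4a, Ccl3, Ccl4 and C4b, have uncertain levels, since reads that map to more than 1 place were handled in a way not given in the sources used here.

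**Figure D2:**
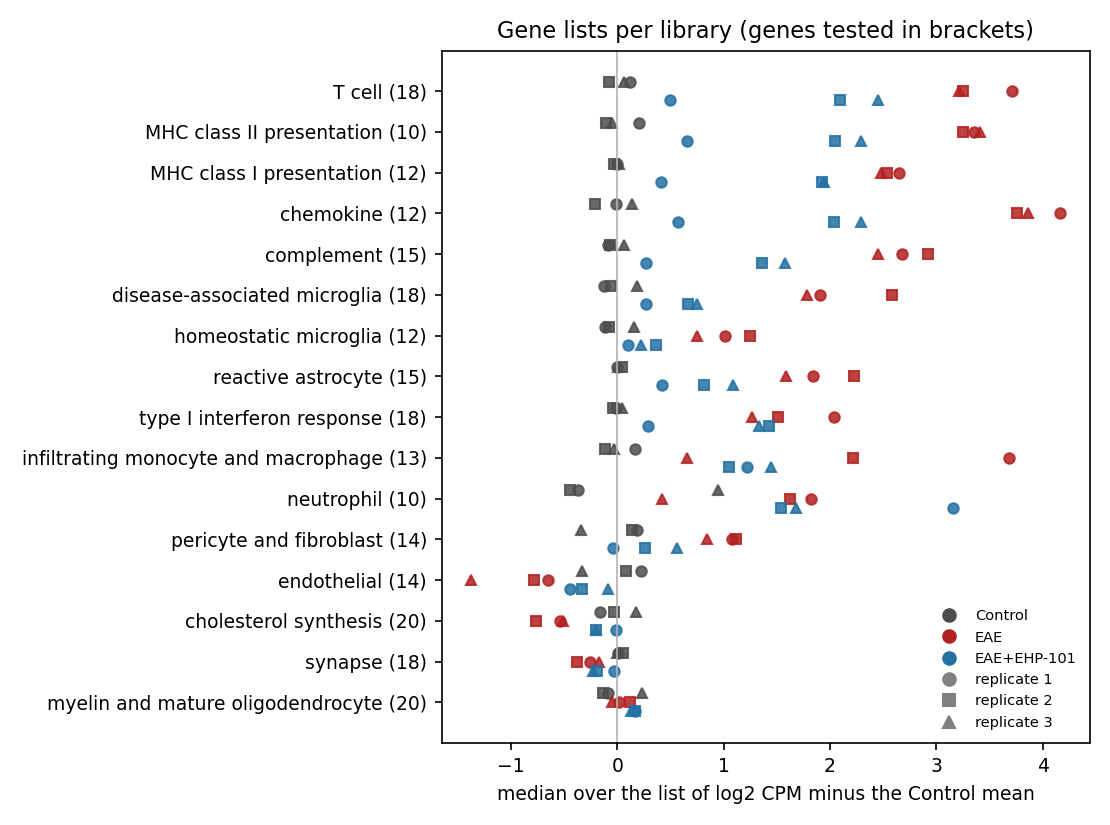
Median over each gene list of log2 CPM minus the Control mean (horizontal axis) for 16 lists (vertical axis, genes tested in brackets), with 1 point per library, coloured by group and shaped by replicate. For the T cell list the treated libraries sit at 0.50, 2.096 and 2.45, between Controls and EAE libraries.

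Treated mice were next compared with untreated EAE mice, which asks what the compound changed in diseased cord. The largest falls included Gpnmb and Lyz2. Gpnmb dropped from 113 ± 35.5 to 10.8 ± 3.999 CPM, lower by 10.5-fold (log2 -3.40, SE 0.26, adjusted p = 0.000218). Lyz2 dropped from 436 ± 91.2 to 43.7 ± 20.5 CPM, lower by 9.99-fold (log2 -3.32, SE 0.30). Col3a1, a fibrillar collagen, was lower by 6.15-fold (log2 -2.62, SE 0.17) at 5.99 ± 1.34 CPM against 4.25 ± 1.04 CPM in Control. Among the rises, Hmcn1, an extracellular matrix protein, was higher by 1.84-fold (log2 0.88, SE 0.12, adjusted p = 0.00239), at 23.1 ± 1.59 CPM against 12.6 ± 1.09 in EAE and 25.6 ± 4.02 in Control. Of 16749 genes 877 passed, 805 lower and 72 higher. At least 2-fold were 397 of the falls against 5 of the rises.

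The other large falls were in Lilrb4a (9.56-fold), Cst7 (9.47-fold), Clec7a (8.77-fold), Itgax (7.19-fold), Cybb (6.09-fold), the matrix gene Postn (5.86-fold) and Ccn5 (5.42-fold), with adjusted p from 0.000261 to 0.00431. All 10 named falls stayed called without any 1 of the 9 libraries. The largest rises were Grpr, the receptor for gastrin-releasing peptide, by 1.85-fold (log2 0.88, SE 0.18, adjusted p = 0.0164), and Hmcn1. After them came the endothelial receptor gene Tie1 (log2 0.84, SE 0.21), Myoc (log2 0.78, SE 0.20), the smooth muscle gene Lmod1 (log2 0.75, SE 0.16), Ccdc187 (log2 0.71, SE 0.13), the semaphorin gene Sema3g (log2 0.71, SE 0.18), Slain1os (log2 0.70, SE 0.17) and Hmgcs1, an early enzyme of cholesterol synthesis (log2 0.67, SE 0.16). Slain1os is named as antisense to Slain1, and without a stated strand setting their reads cannot be told apart. Hmcn1 kept its call in all 9 leave-outs. The other rises named here did not. Grpr ended without EAE replicate 3 (adjusted p = 0.0558) and Ccdc187 without EAE replicate 2 (adjusted p = 0.0513). Lmod1 ended without EAE replicate 2 or treated replicate 1 or 3 (highest adjusted p = 0.0838). Hmgcs1 ended without EAE replicate 1 or 2 or treated replicate 1 or 2 (highest adjusted p = 0.130). Tie1 and Sema3g each ended in 6 leave-outs, shared by Control replicate 2, EAE replicates 2 and 3 and treated replicates 2 and 3, with treated replicate 1 for Tie1 and EAE replicate 1 for Sema3g (highest adjusted p = 0.138 and 0.142). Myoc and Slain1os each ended in 7, shared by Control replicate 2, EAE replicates 2 and 3 and all 3 treated replicates, with Control replicate 1 for Myoc and EAE replicate 1 for Slain1os (highest adjusted p = 0.194 and 0.156). Other settings also ended 4 of these calls. Tie1 ended under library totals (adjusted p = 0.0547), upper quartile factors (0.0505), limma voom (0.0552) and the length correction (0.0507). Sema3g ended under library totals (adjusted p = 0.0539), limma voom (0.0527) and the length correction (0.0518). Myoc ended under library totals (adjusted p = 0.0511), DESeq2 (0.0706) and the GC correction (0.0610), and Slain1os with only the 6 libraries of the 2 groups (0.0548).

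Microglial, complement and astrocyte lists fell with the compound. Disease-associated microglia genes were lower in 16 of 18 (17 adjusted over the list alone), with a median of 2.74-fold. They included Ctsd (log2 -1.45, SE 0.15), Axl (log2 -0.75, SE 0.09) and Apoe, the main apolipoprotein of the central nervous system (log2 -1.41, SE 0.17). Homeostatic microglia genes were lower in 7 of 12 (8 adjusted over the list alone), with Fcrls (log2 -1.35, SE 0.20) and the purinergic receptor gene P2ry13 (log2 -0.81, SE 0.12). All 15 complement genes fell (15 adjusted over the list alone), with C3ar1 (log2 -2.04, SE 0.27), Itgb2 (log2 -1.72, SE 0.23) and C1qb (log2 -1.46, SE 0.20). Reactive astrocyte genes fell in 12 of 15 (15 adjusted over the list alone), with Serpina3n (log2 -1.72, SE 0.23), Emp1 (log2 -0.80, SE 0.12) and Vim (log2 -1.27, SE 0.21). Gfap was at log2 -0.37 (SE 0.15, adjusted p = 0.252). Set test adjusted p were 1.43e-23, 2.70e-09, 6.99e-20 and 4.59e-17. The same lists had adjusted p = 0.144, 0.149, 0.144 and 0.144 with an estimated correlation. Treated replicate 1 had the lowest median of the treated libraries in each of them. For complement it was log2 0.27 against 1.36 and 1.57 in treated replicates 2 and 3. Homeostatic astrocyte genes had 1 of 12 lower (2 adjusted over the list alone), Aldh1l1, whose call ended without any treated replicate, EAE replicate 1 or 2 or Control replicate 1 or 2 (highest adjusted p = 0.237), under library totals (0.0567), upper quartile factors (0.0619) and with only the 6 libraries (0.0657). The list passed downward at adjusted p = 0.00204 (adjusted p = 0.144 with an estimated correlation).

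Lymphocyte and signalling lists also moved down, with fewer single genes past the threshold. In the T cell list 6 of 18 (17 adjusted over the list alone) genes fell, Cd3g (log2 -2.71, SE 0.42) first. Cd4 was at log2 -1.30 (SE 0.43, adjusted p = 0.128). Infiltrating monocyte and macrophage genes fell in 5 of 13 (6 adjusted over the list alone), with Ms4a7 (log2 -3.47, SE 0.25) and Plac8 (log2 -1.51, SE 0.22). B and plasma cell genes fell in 1 of 4 (2 adjusted over the list alone), with Cd22 (log2 -2.50, SE 0.44). MHC class II genes fell in 4 of 10 (10 adjusted over the list alone), with H2-DMa (log2 -1.13, SE 0.20), and MHC class I genes fell in 3 of 12 (11 adjusted over the list alone). Interferon lists had 2 of 18 type I genes lower (5 adjusted over the list alone) and 1 of 13 gamma genes, Irf1 (3 adjusted over the list alone). The call of Irf1 ended without any Control or EAE replicate or treated replicate 2 (highest adjusted p = 0.144), under library totals (0.0576), upper quartile factors (0.0538) and with only the 6 libraries (0.0747). Chemokine genes fell in 6 of 12 (9 adjusted over the list alone), with Ccl4 (log2 -2.64, SE 0.26), Ccl3 (log2 -2.65, SE 0.32) and Cxcl16 (log2 -1.97, SE 0.32). Cytokine genes fell in 5 of 9 (6 adjusted over the list alone), with Tgfb1 (log2 -1.003, SE 0.15) and Il1a (log2 -1.23, SE 0.21). Adhesion genes fell in 5 of 12 (10 adjusted over the list alone), with Itgb7 (log2 -1.13, SE 0.20) and Icam1 (log2 -1.32, SE 0.25). Alternative macrophage genes fell in 4 of 10 (4 adjusted over the list alone), with Msr1 (log2 -3.09, SE 0.37), and proliferation genes in 2 of 17 (4 adjusted over the list alone). These 12 lists passed at adjusted p from 7.92e-13 (T cell) to 0.00851 (B and plasma cell). With an estimated correlation they had adjusted p = 0.144 (proliferation, cytokine and adhesion) to 0.298 (type I interferon). The B and plasma cell call ended without EAE replicate 1 (adjusted p = 0.0534). In 11 of these 12 lists, all but the monocyte and macrophage list, treated replicate 1 had the lowest median of the treated libraries. The median over the T cell genes was log2 0.50 against 2.096 and 2.45 in treated replicates 2 and 3. That over the type I interferon genes was 0.29 against 1.43 and 1.33.

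In the set test the pericyte and fibroblast list moved down and the cholesterol synthesis and endothelial lists up. Pericyte and fibroblast genes were lower in 7 of 14 (9 adjusted over the list alone), with Lum (log2 -2.14, SE 0.22), Col1a2 (log2 -0.79, SE 0.09) and Col1a1 (log2 -1.61, SE 0.20). The set test gave adjusted p = 4.94e-08 (adjusted p = 0.178 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 20 (20 adjusted over the list alone), with Sqle (log2 0.53, SE 0.10), at a median of 1.39-fold and adjusted p = 3.87e-19 (adjusted p = 0.149 with an estimated correlation). Of the endothelial genes 1 of 14 (9 adjusted over the list alone) rose, Tie1, at adjusted p = 1.02e-07 for the list (adjusted p = 0.214 with an estimated correlation). The myelin list had 1 of 20 higher (2 adjusted over the list alone), Fa2h, an enzyme of myelin lipid synthesis (log2 0.35, SE 0.08, adjusted p = 0.0270), whose call ended without any EAE replicate or treated replicate 1 or 2 (highest adjusted p = 0.0995). It passed upward at a median of log2 0.12 (adjusted p = 0.000312, and adjusted p = 0.392 with an estimated correlation), with Mbp at log2 0.14, SE 0.11, adjusted p = 0.593. Neuron and synapse lists passed upward at medians of log2 0.09 and 0.10 with 0 of 14 and 0 of 18 genes called by edgeR (0 and 0 adjusted over the list alone). They had adjusted p = 0.0176 and 0.00292, and adjusted p = 0.481 and 0.430 with an estimated correlation. The neuron call ended without EAE replicate 1 (adjusted p = 0.0564), EAE replicate 2 (0.0934) or treated replicate 1 (0.0722). The synapse call ended without EAE replicate 2 (0.0934) or treated replicate 1 (0.0753). Tenm4 (log2 0.41, SE 0.14, adjusted p = 0.162), Gjc3 (log2 0.26, SE 0.07, adjusted p = 0.0557) and Olig2 (log2 0.13, SE 0.13, adjusted p = 0.697) were 0 of 3 called (2 adjusted over the list alone, which is not independent evidence, since the study chose them on these samples), and passed together at adjusted p = 0.0135 (adjusted p = 0.149 with an estimated correlation).

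The neutrophil list moved against the other immune lists. Its set test was upward (adjusted p = 0.0311, and adjusted p = 0.439 with an estimated correlation) at a median of log2 0.96, while its 1 called gene of 10 (1 adjusted over the list alone), Csf3r, fell (log2 -1.02, SE 0.22, adjusted p = 0.0209). The median over neutrophil genes was log2 3.15 in treated replicate 1 and 1.54 and 1.68 in the other treated libraries. The list's call ended without treated replicate 1 (adjusted p = 0.312), EAE replicate 3 (0.454), Control replicate 2 (0.0648) or Control replicate 3 (0.0579). The call of Csf3r ended without EAE replicate 1 (0.0795), EAE replicate 2 (0.106) or treated replicate 2 (0.0513).

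In all, 28 of the 43 lists passed, 21 downward and 7 upward, none with an estimated correlation (adjusted p 0.144 to 0.481). With fry 20 of them passed, and those for neutrophils (adjusted p = 0.378), neurons (0.335), synapses (0.291), myelin (0.248), endothelium (0.107), type I interferon (0.107), interferon gamma (0.107) and B and plasma cells (0.0607) did not. The lists for progenitors (0.571), motor neurons (0.402), interneurons (0.1001), neuronal injury (0.0637), cilia (0.152), Schwann cells (0.571), dorsal root ganglion (0.729), erythroid cells (0.639), muscle (0.756), glucocorticoid response (0.642), immediate early genes (0.401), heat shock (0.140), respiration (0.536) and mitochondrially encoded genes (0.536) did not pass. Median and mean differed in sign for the Schwann cell (0.03 and -0.04), dorsal root ganglion (0.03 and -0.13) and mitochondrially encoded (0.06 and -0.03) lists. The count of 877 genes was 495 without EAE replicate 1, 370 without EAE replicate 2, 575 without treated replicate 1 and 529 without treated replicate 2. The 72 rises became 249 without Control replicate 3, 31, 22 and 46 without EAE replicates 1, 2 and 3, 28, 28 and 43 without treated replicates 1, 2 and 3, 137 with DESeq2 and 169 with only the 6 libraries of the 2 groups. The 805 falls became 464 and 348 without EAE replicates 1 and 2 and 501 without treated replicate 2.

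**Figure D3:**
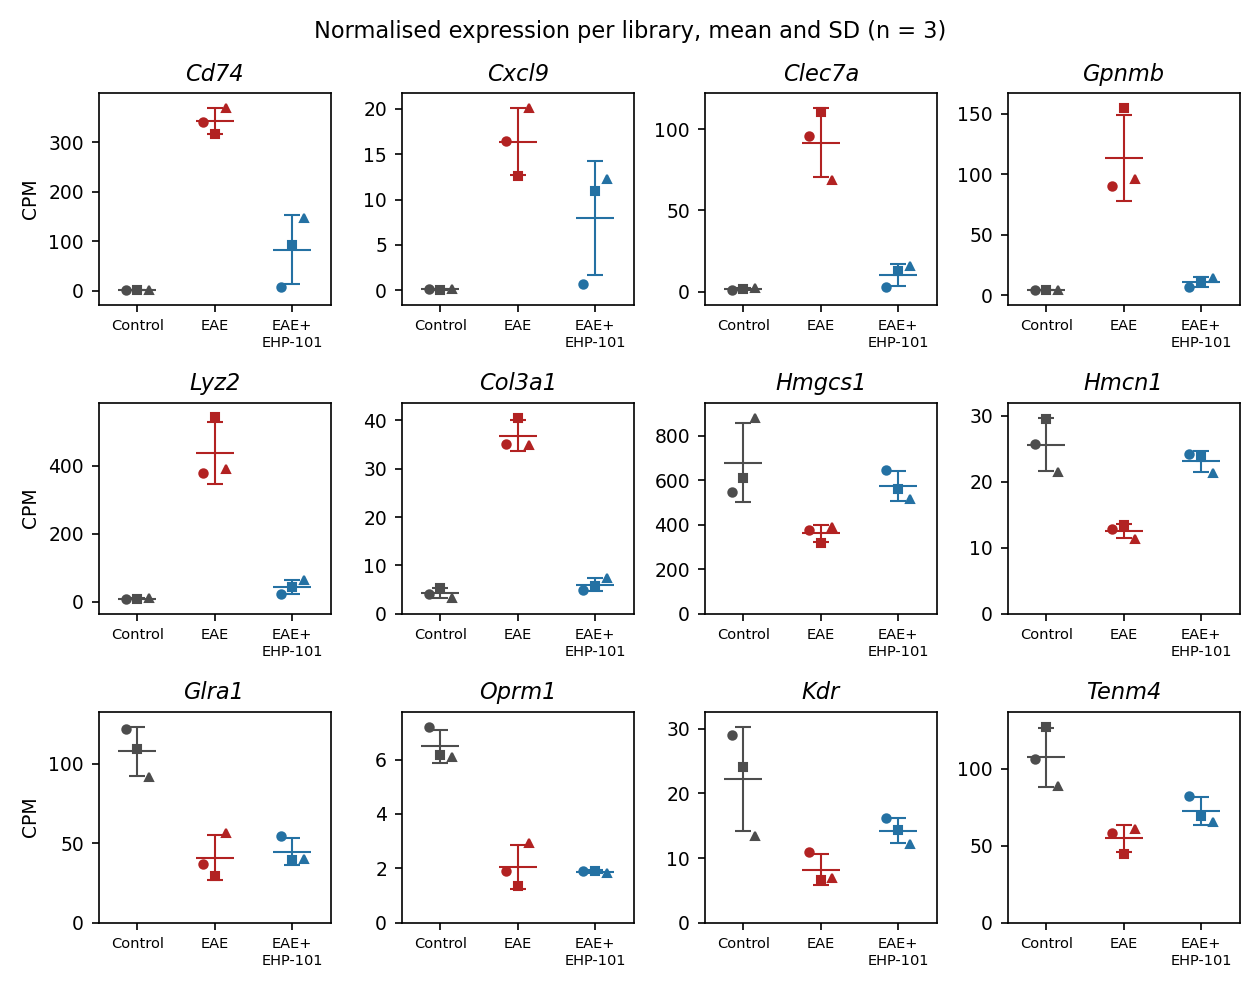
CPM (vertical axes, from 0) of 12 genes in Control, EAE and EAE+EHP-101, with points for the 3 libraries of each group and bars for mean and SD. Gpnmb averaged 4.26 ± 0.143, 113 ± 35.5 and 10.8 ± 3.999 CPM in the 3 groups, and Oprm1 6.49 ± 0.614, 2.06 ± 0.805 and 1.88 ± 0.0513.

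Treated mice were then compared with Control, which asks what distance from Control cord was left. Class II genes remained raised, with Cd74 higher by 41.4-fold (log2 5.37, SE 0.85, adjusted p = 0.00494) at 82.8 ± 69.7 CPM. The treated libraries differed among themselves, at 8.41, 93.4 and 147 CPM. Cxcl9 was higher by 88.1-fold (log2 6.46, SE 1.14) and Cybb by 8.81-fold (log2 3.14, SE 0.55). Oprm1 was lower by 3.44-fold (log2 -1.78, SE 0.22, adjusted p = 0.00432) and Glra1 (gene 14654, chromosome 11 from 55514813 to 55607790) by 2.41-fold (log2 -1.27, SE 0.21), at 44.7 ± 8.54 CPM against 108 ± 15.3 in Control. Of 16749 genes 3314 passed, 1669 higher and 1645 lower, with 347 rises and 73 falls of at least 2-fold.

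Among the 10 largest rises stood also H2-Aa (39.3-fold), H2-Ab1 (33.7-fold), H2-Eb1 (18.9-fold) and Itgax (9.96-fold). Others were Ccn5 (9.14-fold), the immunoglobulin receptor gene Fcgr4 (8.26-fold) and the integrin gene Itgal (7.42-fold), with adjusted p from 0.00576 to 0.00843. With limma voom in place of edgeR the calls of Cxcl9 (adjusted p = 0.0923), Cd74 (0.0724), H2-Aa (0.108), H2-Ab1 (0.103) and H2-Eb1 (0.0619) ended. All 10 rises kept theirs in the 9 leave-outs under edgeR. The largest falls besides Oprm1 and Glra1 were Pkd1l2 (log2 -1.56, SE 0.46), the dynein gene Dnah11 (log2 -1.53, SE 0.29), Fam216b (log2 -1.52, SE 0.35), Frem3 (log2 -1.45, SE 0.34), the dynein gene Dnah6 (log2 -1.42, SE 0.39), Hydin, a protein of motile cilia (log2 -1.38, SE 0.32), and Samd5 (log2 -1.30, SE 0.18). Calls ended for Fam216b without Control replicate 2 (adjusted p = 0.0501), for Hydin without Control replicate 2 or treated replicate 2 (highest 0.0769) and for Frem3 without those or treated replicate 3 (highest 0.0624). Those of Pkd1l2 and Dnah6 ended without Control replicate 2 or any treated replicate (highest 0.140 and 0.109). Removing the length trend ended the calls of Pkd1l2 (adjusted p = 0.0801) and Dnah6 (0.0840).

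The 13 lists given first remained above Control, each at a smaller median than in EAE. T cell genes were higher in 14 of 18 (17 adjusted over the list alone), with Cd3e (log2 3.37, SE 0.67) and Cd6 (log2 4.11, SE 0.88). Monocyte and macrophage genes were higher in 7 of 13 (7 adjusted over the list alone), with Plac8 (log2 2.32, SE 0.32) and Lyz2 (log2 2.22, SE 0.31). MHC class I genes were higher in 12 of 12 (12 adjusted over the list alone), with H2-K1 (log2 1.86, SE 0.31) and H2-D1 (log2 1.70, SE 0.29), and class II genes in 8 of 10 (9 adjusted over the list alone). Type I interferon genes were higher in 12 of 18 (17 adjusted over the list alone), with Bst2 (log2 1.68, SE 0.28), and interferon gamma genes in 11 of 13 (11 adjusted over the list alone), with Cxcl10 (log2 2.74, SE 0.51). Complement genes were higher in 11 of 15 (14 adjusted over the list alone), with C4b (log2 1.24, SE 0.19) and C1qa (log2 1.46, SE 0.23). Chemokine genes were higher in 8 of 12 (9 adjusted over the list alone), with Ccl12 (log2 3.34, SE 0.42) and Ccl5 (log2 4.73, SE 0.77). Cytokine genes were higher in 3 of 9 (6 adjusted over the list alone), adhesion genes in 5 of 12 (9 adjusted over the list alone), with Itgb7 (log2 1.23, SE 0.23). Disease-associated microglia genes were higher in 12 of 18 (15 adjusted over the list alone), with Lgals3 (log2 1.72, SE 0.25) and Itgax. Reactive astrocyte genes were higher in 8 of 15 (11 adjusted over the list alone), with Lcn2 (log2 2.18, SE 0.37) and Ptx3 (log2 1.42, SE 0.25), and proliferation genes in 3 of 17 (3 adjusted over the list alone). These 13 lists passed at adjusted p from 2.66e-06 (T cell) to 0.0155 (proliferation). They had adjusted p = 0.611 with an estimated correlation for each. Neutrophil genes were higher in 8 of 10 (9 adjusted over the list alone), with Camp (log2 2.40, SE 0.56) and Csf3r (log2 1.06, SE 0.24), at adjusted p = 0.000160 (adjusted p = 0.611 with an estimated correlation) and a median of log2 2.23 against 1.24 in EAE. By library the medians were 3.15, 1.54 and 1.68 in treated and 1.82, 1.62 and 0.42 in EAE replicates 1, 2 and 3. Treated replicates 2 and 3 thus lay within the EAE range. The call of Camp ended without Control replicate 2 (0.0629) or treated replicate 2 (0.0564). That of Csf3r ended without Control replicate 2 (0.0501) or treated replicate 2 (0.0684) or 3 (0.0599). The MHC class I median over Control was log2 0.41 in treated replicate 1 against 1.93 and 1.95 in the other treated libraries. The interferon gamma median was log2 0.10 in treated replicate 1, below the 0.13 of Control replicate 3. It was 1.27 and 1.70 in treated replicates 2 and 3, so the rise of this list rested on those libraries.

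Neural and vascular lists were mixed. Synapse genes were lower in 8 of 18 (8 adjusted over the list alone), with Gabrb2 (log2 -0.68, SE 0.09), at adjusted p = 0.00120 (adjusted p = 0.611 with an estimated correlation), and in 5 of 18 with the length trend removed, where the list passed at 0.0173 (adjusted p = 0.534 with an estimated correlation). Myelin genes were higher in 5 of 20 (7 adjusted over the list alone), with Mag, a myelin adhesion protein (log2 0.34, SE 0.06), at adjusted p = 0.00272 (adjusted p = 0.611 with an estimated correlation). Respiration genes were higher in 9 of 20 (11 adjusted over the list alone) (adjusted p = 0.00107, and adjusted p = 0.611 with an estimated correlation), and in 0 of 20 with the length trend removed, which ended the call (adjusted p = 0.957). Their 4 first genes by p, Cox4i1, Ndufa2, Cox6c and Uqcrc1, lost their calls with the length trend removed (adjusted p = 0.329, 0.210, 0.397 and 0.205). Cox6c also lost its call without treated replicate 2 (0.0720) or 3 (0.0527) and Uqcrc1 without any treated replicate or Control replicate 2 (highest 0.0773) or with the GC trend removed (0.103). Cholesterol synthesis genes had 0 of 20 called by edgeR (0 adjusted over the list alone) at a median of log2 -0.15. The list passed downward at adjusted p = 0.0462 (adjusted p = 0.696 with an estimated correlation). This ended under library totals (0.0519) and without Control replicate 3 (0.583), treated replicate 2 (0.106) or treated replicate 3 (0.149). Endothelial genes, with 0 of 14 called by edgeR (0 adjusted over the list alone), passed downward at 0.0460 (adjusted p = 0.684 with an estimated correlation). This ended without Control replicate 1 (0.304) or 2 (0.139), EAE replicate 2 (0.0540) or treated replicate 1 (0.192). Cilia genes were lower in 2 of 9 (2 adjusted over the list alone), Dnah11 and Ak7 (log2 -1.08, SE 0.30), at adjusted p = 0.0434 (adjusted p = 0.657 with an estimated correlation), ending without Control replicate 2 (0.139) or 3 (0.134) or treated replicate 1 (0.171). The call of Ak7 ended without Control replicate 2 or any treated replicate (highest 0.105). Glucocorticoid response genes, 0 of 12 called (5 adjusted over the list alone), passed upward at 0.0494 (adjusted p = 0.611 with an estimated correlation). This ended under library totals (0.0639), with the length trend (0.0906) or the GC trend (0.124) removed and without Control replicate 3 (0.163) or treated replicate 3 (0.151). Tenm4 was lower by 1.48-fold (log2 -0.57, SE 0.14, adjusted p = 0.0205), a call that ended without Control replicate 2 (0.0669) or treated replicate 2 (0.0891) or 3 (0.0820) and with the length trend removed (0.103). Gjc3 (log2 -0.06, SE 0.07, adjusted p = 0.583) and Olig2 (log2 0.15, SE 0.13, adjusted p = 0.441) were not called (1 of 3 lower, 1 adjusted over the list alone, in genes the study chose on these samples and so not independent evidence).

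In all, 21 of the 43 lists passed against Control, 17 upward and 4 downward, none with an estimated correlation (adjusted p 0.611 to 0.696). With fry 1, proliferation, passed, and the other 20 had adjusted p from 0.0892 to 0.429. Those for B cells (0.124), homeostatic microglia (0.124), homeostatic astrocytes (0.192), progenitors (0.924), neurons (0.909), motor neurons (0.40002), interneurons (0.229), neuronal injury (0.523), pericytes and fibroblasts (0.279) and alternative macrophage activation (0.0966) did not pass. Neither did those for Schwann cells (0.710), dorsal root ganglion (0.523), erythroid cells (0.292), muscle (0.236), immediate early genes (0.349), heat shock (0.644) and mitochondrially encoded genes (0.492). The count of 3314 genes was 1923 without Control replicate 2, 629 without treated replicate 2, 1016 without treated replicate 3 and 1553 with the length trend removed. The 1669 rises became 942 and 623 without Control replicates 1 and 2, and 237 and 427 without treated replicates 2 and 3, where the 1645 falls became 392 and 589. Removing the GC trend left 1031 rises, and removing the length trend 760 rises and 793 falls. Median and mean differed in sign for the progenitor (0.09 and -0.00) and Schwann cell (-0.01 and 0.61) lists. Scaling by library totals gave 2176 higher and 1319 lower genes, 62.3% higher against 50.4% with the main scaling.

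The last comparison joined the first 2, to ask how far the genes changed in EAE moved toward Control with the compound. Among genes higher in EAE, 790 fell in treated mice, which is 98.1% of all 805 falls. Among genes lower in EAE 56 rose, 77.8% of the 72 rises, with 0 genes changed further in the same direction. Independent lists of these sizes would share 163 and 12.04 genes. Gpnmb, Lyz2, Lilrb4a, Cst7, Clec7a, Itgax, Col3a1, Cybb, Postn and Ccn5 had the largest falls among them. Grpr, Hmcn1, Tie1, Lmod1, Ccdc187, Sema3g, Slain1os, Hmgcs1 and Smtnl2 (log2 0.64, SE 0.12, adjusted p = 0.0115, a call that ended without EAE replicate 2 at 0.0538) had the largest rises. Col3a1 came back nearly to its Control level (log2 0.49, SE 0.19, adjusted p = 0.0861 against Control), while Cxcl9 was not called between treated and EAE mice (log2 -1.04, SE 0.58, adjusted p = 0.426).

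The EAE libraries enter both comparisons, which alone makes their changes run opposite. In 50 simulated data sets with no difference between groups 0 genes were moved back, and with EAE and treated mice drawn at their common mean 0.32 genes on average. Such data give almost no calls between EAE and treated mice. These counts thus could not show how many of the real calls run opposite only because the EAE libraries are shared. Across genes, which are not independent replicates, the fold changes of the 2 comparisons had a covariance of -0.238 and a correlation of -0.828. Simulated without differences these were -0.0194 and -0.497, and with EAE and treated mice at their common mean -0.0197 and -0.147. Part of the excess may come from the shared EAE libraries, since 3 libraries cannot be split into parts of at least 2. The share of the EAE change left in treated mice was taken as a ratio of log2 fold changes, not of CPM. Its median was 56.6% over the 3391 higher genes and 75.6% over the 2800 lower genes, against 94.96% and 92.6% in simulated data with EAE and treated mice at their common mean. By treated library these medians were 35.6%, 65.7% and 65.4% for the higher genes and 55.6%, 86.1% and 86.3% for the lower. The 846 genes moved back became 489 without EAE replicate 1, 364 without EAE replicate 2 and 524 without treated replicate 2. Against Control, 1489 genes were higher and 1471 lower in both EAE and treated mice, where independent lists would share 338 and 275. The simulation without differences shared 0, which data with almost no calls give in any case. Here too part of the excess may come from the shared Control libraries. The covariance of these fold changes was 0.323 against 0.0196 simulated.

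**Figure D4:**
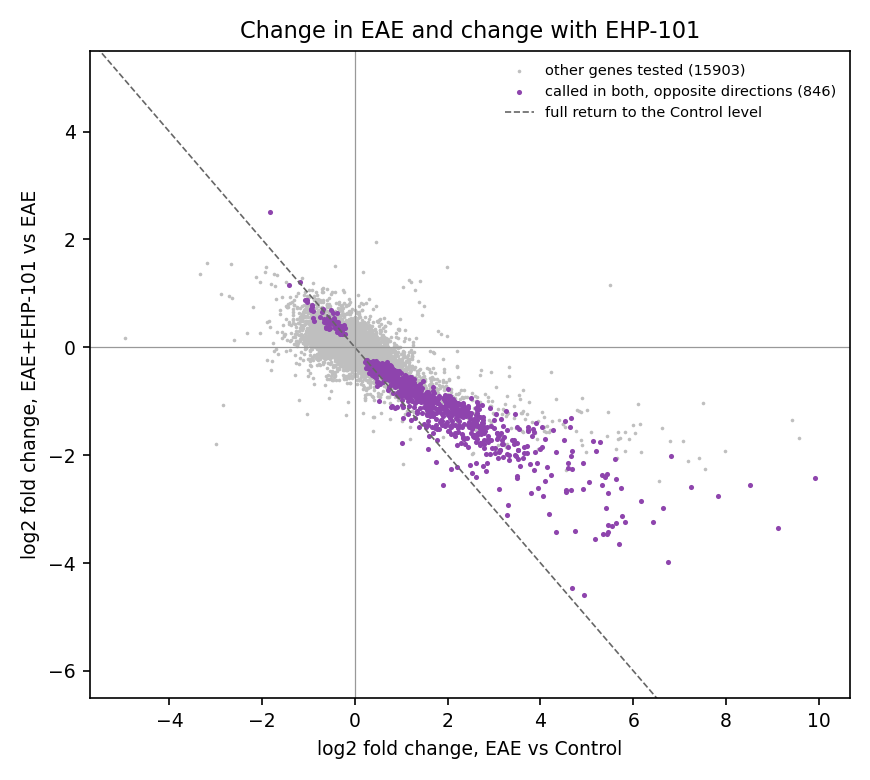
Log2 fold change in EAE against Control (horizontal axis) and in EAE+EHP-101 against EAE (vertical axis), with 1 point per gene tested and a dashed line for a full return to the Control level. The 846 coloured genes were called in both comparisons in opposite directions, and the other genes are grey.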

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

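The tests with the length and GC corrections were chosen after the result was seen. Over 615 pairs of a named gene and a contrast, 12281 values under the alternatives gave 11434 on the same side of the threshold, 598 no longer past it, 249 newly past it and 0 in the opposite direction. Of the 598, 436 came from leaving out 1 library, 44 from the length correction, 32 from the block on replicate number and 27 from the GC correction. A minimum of 2-fold left 1185 genes for EAE against Control, 402 for EAE+EHP-101 against EAE and 420 for EAE+EHP-101 against Control, fewer by construction. Without 1 library the counts ranged from 4378 to 7095, from 370 to 1170 and from 629 to 3739, the genes moved back from 364 to 1082, and the lists called from 22 to 27, 25 to 29 and 19 to 22. In the set tests the length correction gave 25, 29 and 22 lists and the GC correction 25, 29 and 21. The length correction ended 2, 0 and 2 of the list calls and gained 3, 1 and 3 others. The length correction left 1553 genes for EAE+EHP-101 against Control, and the cause was not tested. With an estimated correlation 0 lists were called in each contrast, and fry called 1 for EAE+EHP-101 against Control. For EAE against Control some calls ended although the estimate was not above or barely above the preset 0.01. The set test of the proliferation list (estimate 0.0114) went from adjusted p = 0.000145 to 0.301. That of the hypoxia list (estimate -0.00351) went from 0.0411 to 0.322. The size of the correlation thus did not end the calls of these lists, and the cause was not tested further. The median share of the EAE change left, by log2 fold changes, ranged from 48.9% to 65.0% for higher and from 68.2% to 86.6% for lower genes when 1 library was left out, and was 47.8% for higher genes with the length correction. The block gave 5345, 722 and 2272 genes, with 44 rises for EAE+EHP-101 against EAE and 1095 for EAE+EHP-101 against Control. Libraries with the same number correlated between -0.187 and 0.123 and those with other numbers between -0.175 and 0.246, with 2 of 18 best matches on the own number, so the numbers were not read as pairs. The other scalings, tests and filters moved no total count by over 1.5 times. DESeq2 gave an adjusted p for 609 of the 615 pairs, the fits of 6 libraries had 602, and the rest were left out. With 3 libraries per group, changes under 2-fold are those the depth and the spread leave most often uncalled.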

Other observations

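The tests of a wrong label by the size of the rise, over the gene lists and by distance, the list medians given beside them, the test of a swap, and those with the length or GC trend removed were chosen after the result was seen. Of the receptors named for the compound Cnr2 was called and Pparg was not. Cnr2 (gene 12802, chromosome 4 from 135895404 to 135920215 in mm10), the cannabinoid receptor of immune cells, rose in EAE by 6.29-fold (log2 2.65, SE 0.23, adjusted p = 3.28e-05) and fell in treated mice (log2 -1.47, SE 0.20, adjusted p = 0.00267), at 0.530 ± 0.0480, 3.35 ± 0.232 and 1.21 ± 0.339 CPM in Control, EAE and EAE+EHP-101. Cnr1, the cannabinoid receptor of neurons, was lower in EAE (log2 -0.40, SE 0.08, adjusted p = 0.00339) and not called between treated and EAE mice (log2 0.03, SE 0.08, adjusted p = 0.917), and its fall against Control (log2 -0.37, SE 0.08, adjusted p = 0.0131) ended without treated replicate 2 (0.0666) or 3 (0.0579) and with the length trend removed (0.0641). Pparg was not called in any of the 3 contrasts (adjusted p = 0.892, 0.891 and 0.719). The endocannabinoid list did not pass (adjusted p = 0.859, 0.729 and 0.819), with medians of -0.06 and 0.03 and means of 0.15 and -0.10, opposite in sign, in the first 2 contrasts.

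The hypoxia list and the NRF2 and oxidative stress list passed upward in EAE and downward in treated against EAE mice. Plin2, a coat protein of lipid droplets, rose (log2 1.003, SE 0.12) and fell (log2 -0.73, SE 0.12), and the PPAR target list passed downward in treated against EAE mice (adjusted p = 0.00184, adjusted p = 0.181 with an estimated correlation) but not in EAE (0.0542) or in treated mice against Control (0.701, median 0.03, mean -0.36, of opposite sign), with 3 of 12 (4 adjusted over the list alone) genes lower. Slc16a3, a lactate transporter, rose (log2 1.54, SE 0.14) and fell (log2 -1.13, SE 0.14), and the hypoxia list had 4 of 16 (4 adjusted over the list alone) genes higher in EAE (adjusted p = 0.0411, adjusted p = 0.322 with an estimated correlation) and 3 of 16 (5 adjusted over the list alone) lower in treated mice (adjusted p = 0.00667, adjusted p = 0.144 with an estimated correlation). The EAE call of that list ended with the GC trend removed (adjusted p = 0.0643) and without Control replicate 2 (0.0775), EAE replicate 2 (0.0531) or EAE replicate 3 (0.0768), and it did not pass against Control in treated mice (0.380). Hmox1, haem oxygenase, rose (log2 1.53, SE 0.14) and fell (log2 -0.99, SE 0.14), as did Ncf1 (log2 2.17, SE 0.17, then log2 -1.24, SE 0.16), a subunit of the phagocyte oxidase. The NRF2 and oxidative stress list had 5 of 14 (5 adjusted over the list alone) higher in EAE (adjusted p = 0.0411, adjusted p = 0.405 with an estimated correlation), a call that ended with the length trend removed (adjusted p = 0.0674) and without Control replicate 2 (0.117) or EAE replicate 3 (0.0769), and 4 of 14 (4 adjusted over the list alone) lower in treated mice (adjusted p = 0.000449, adjusted p = 0.178 with an estimated correlation), and did not pass against Control (0.292).

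Xist was between 614 and 817 CPM in all 9 libraries and Ddx3y between 0 and 0.0957. The mitochondrial genes mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l had mean counts of 7.78 to 204 against 44955.9 to 358025 for the others, so their levels are uncertain.

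Of the treated libraries replicate 1 lay nearest the Controls, at a chi-square per degree of freedom of 19.1 to 22.8 from them. It lay nearer to treated replicates 2 and 3, at 10.03 and 12.4. Control replicate 3 lay 26.1 and 23.8 from Control replicates 1 and 2, farther than treated replicate 1, at 19.1 from each. A Control library under a treated label was argued against, since every Control lay at least 33.9 from treated replicates 2 and 3. This was 21.5 above the largest value of treated replicate 1, where the Control values ranged over 6.51. In log2 CPM the gap was 11.6 against a range of 7.64. The neutrophil and MHC class I medians of treated replicate 1, log2 3.15 and 0.41, also lay above every Control (at most 0.95 and 0.02). However, 3 other tests of the label, over genes or lists raised in EAE, did not reach their bounds. The first gave 7.13 points where over 10 was set, and the second 1.53 times where over 2 was set. The last counted lists above every Control by more than the range of the Controls. It gave 11 of 21 lists, against 10 for a left-out Control set beside the other Controls, where over 2 times was set. For a swap with 1 of the 3 Controls, no Control passed the bound over genes raised in EAE (highest median 0.0876, where over 0.5 was set). That bound could miss a treated library near the Controls, since treated replicate 1 itself had medians of only log2 0.222 to 0.236 over such genes. The test thus did not decide about a swap. A mouse that responded more and a mixed sample stay open, and neither was tested.

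Genes that fell in EAE had a median exonic length of 4771 bases against 1886 for genes that rose. A GC trend between libraries was argued against as the whole cause, since 0.856 of the falls were kept with it removed. A length trend stays open, since 0.516 of the falls were kept, between the 0.5 and 0.67 set. The 1444 kept falls had a median log2 of -0.53 before and -0.47 after the correction. They were selected as still called, so this median could not have been near 0 and does not weigh on the cause. The 1356 lost falls went from a median log2 of -0.30 (SE 0.07) to -0.12 (SE 0.07), so their calls ended because the change shrank.

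In treated libraries the median excess over Control left, in CPM, was 16.6% (SD 10.3) for disease-associated microglia genes and 42.1% (SD 28.3) for MHC class I genes, as the mean of 3 libraries. On the log2 scale these means were 31.9% and 56.4%. MHC class I minus disease-associated microglia was 4.44, 36.4 and 35.5 points in treated replicates 1, 2 and 3. In EAE replicates 1, 2 and 3 it was 22.9, -49.0 and 14.2 points. A common fall in the cells that bring the rise was set to keep the difference within the largest size among EAE libraries, 49.0, which it did. This lends no weight to such a fall. In treated replicate 1 only 4.98% (disease-associated microglia) and 9.41% (MHC class I) of the excess was left, so its difference could not reach 49.0. Noise of low-count genes met its prediction through treated replicate 1 alone. Among abundant members (4 of MHC class I and 9 of disease-associated microglia) its difference was -0.911 points. Treated replicates 2 and 3 kept 29.6 and 30.8 points, and the largest size among EAE libraries was 46.5, so this was not decided either. The pattern was thus not separated from the spread between EAE libraries.

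For each contrast 1 of 10 splits of the 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real splits gave 5390, 921 and 2518 genes for EAE against Control, EAE+EHP-101 against EAE and EAE+EHP-101 against Control, and the highest other splits 0, 1 and 0.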
